A study of Mus musculus with 20 samples.

How the data were processed

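RNA was measured in the cortex of 3-month-old C57BL/6 mice, wild type or with a heterozygous Foxp2 deletion, 1 animal per sample. Per the labels' protocols, cortical hemispheres were freed of diencephalon, basal ganglia, hippocampus and a rostral tip, ribosomes carrying a GFP tag were pulled down with anti-GFP serum (bacTRAP, here IP), and part of the same animal's lysate was set aside just before the pull-down (Input). Smart-seq2 libraries were then made. This protocol marks neither strand nor single molecules, so counting errors understate the real error and overlapping genes cannot be told apart. Which cells carry the GFP tag is not given in the sources used here.

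The authors deposited raw read counts per Ensembl gene for 20 libraries of 10 animals, made with HTSeq on mm10 per the submitters' processing notes. The HTSeq version, aligner, annotation release and strand setting are not given. All values were checked to be whole numbers at or above 0. The table has 25317 gene identifiers, of which 24873 were matched to a gene name and 444 were not. Totals ran from 2689544 to 5754169 counts per library: 2782934 to 4072270 in heterozygous Input, 3391291 to 3934152 in wild-type Input, 4917886 to 5337469 in heterozygous IP and 4061562 to 5754169 in wild-type IP.

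Animals are named by genotype and the number in their titles, such as het729 and wtBT13. IP and Input were compared in 8 animals, 3 heterozygous (het729, het786, hetBT13) and 5 wild type (wt734, wt736, wt785, wtBT13, wtBT14). Another 4 heterozygous libraries, from het730 and hetBT14, carry the label Input but end in IX or IXX in their titles, and those animals have no IP, so they were left out of the comparisons and used in alternatives. IP and Input libraries of an animal were paired because the protocol takes both from 1 lysate. After group means were removed, the pairs correlated across 10865 genes with r from 0.053 to 0.311. In 6 of 8 animals this was above the highest r with another animal of the same genotype, the exceptions being het786 (0.053 against 0.088) and wtBT14 (0.078 against 0.258). Deviations from a group mean sum to 0, which lowers r with the rest of the group where that of the pair is positive. The comparison therefore leans towards the pair.

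Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were filtered with filterByExpr (count minimum of 10), scaled with TMM, and tested with robust quasi-likelihood F tests at a Benjamini-Hochberg adjusted p below 0.05. Genotype was tested in IP and in Input separately, 3 against 5 libraries. IP against Input was tested in each genotype, and the difference of the genotype effects between fractions, in 1 fit of 16 libraries with animal as a block. CPM are TMM-scaled, and errors are SD over animals. Single values were compared with two-sided exact permutation tests. Principal components used log2 CPM with a prior count of 1.

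Gene lists, 34 in all, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with adjustment over the lists of a comparison, and again with an estimated correlation and with fry. Lists with fewer than 3 tested genes were left untested. The lists cover cortical layers (6 corticothalamic, 6b, 5, upper), glutamatergic neurons, interneurons, astrocytes, oligodendrocytes and their precursors, microglia, endothelium, mural cells, choroid plexus, blood, striatum, hippocampus, thalamus, dopamine signalling, genes linked to Foxp2 in earlier work, social behaviour and autism, genes near Foxp2, presynaptic genes, glutamate receptors, GABA receptors, ion channels, axon guidance, immediate early, heat shock, mitochondrially encoded, oxidative phosphorylation, ribosomal protein, nuclear RNA, sex-linked and cholesterol synthesis genes. They were written from general knowledge, except that Apba2 was put on the social behaviour and presynaptic lists from knowledge of the study, and share some members.

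Named genes followed a rule: Foxp2, Foxp1, Foxp4, Drd1, Apba2, Ntsr1 and Cntnap2 everywhere; in genotype comparisons the 10 largest called changes per direction with a mean CPM of at least 5 and no overlap between groups, or the 5 of smallest p where fewer than 5 passed; in wild-type IP against Input the 10 largest called changes per direction with that level and the same direction in all 8 animals; and up to 4 members of smallest p of each list that passed. Genes passing adjusted over the list alone that are outside the rule (Fgfr3, Cav2 and Itm2a in Input, Matn4 in the interaction) were chosen after their values were seen. Comparisons, tests, lists, this rule and the alternatives not marked otherwise were fixed before the data were examined.

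Each fit was tested on simulated data with the same totals and groups and 200 changed genes. Of genes changed by 1.5, 2 and 3 fold, the genotype fit in IP recovered 23.1%, 65.7% and 84.8% (5 of 120 calls false), that in Input 42.4%, 90.5% and 92.3% (17 of 162), the wild-type enrichment 56.7%, 83.1% and 95.5% (9 of 164), the heterozygous enrichment 44.8%, 69.2% and 92.4% (9 of 145) and the interaction 19.4%, 64.2% and 70.3% (8 of 109). In each fit 0 of 30 unchanged lists passed camera. The simulated genes vary independently of each other, so this does not cover the correlation of real genes: with the real libraries in other splits, a median of 9 lists passed in IP and 8 in Input.

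Alternatives were RLE size factors, library totals alone, DESeq2 1.42.0, limma-voom, no low-count filter, a stricter filter (CPM of at least 5 in at least 3 libraries), leaving out each animal, the form of the animals' names (BT or number only) as a covariate, a 4-group fit of 16 libraries without a block, and the IX and IXX libraries summed per animal. After the data were examined, covariates for mitochondrially encoded RNA (IP) and haemoglobin RNA (Input) were added, and a fit with the IX and IXX libraries but without het729 and het730. The labels give no batch, so the form of the names stood in for one. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.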

Results

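Foxp2 (ENSMUSG00000029563, chromosome 6, 14901349 to 15441977 in mm10, plus strand), which encodes the forkhead transcription factor whose deletion defines the groups, was lower on average in heterozygotes than in wild types in both fractions. In the lysate before pull-down (Input), heterozygotes had 27.6 ± 3.44 CPM (library-scaled counts, SD, n = 3) and wild types 46.8 ± 10.8 (n = 5), 59.1% of the wild-type level (exact permutation test, two-sided, p = 0.0357; the smallest p the design allows is 0.0179). In the ribosome-bound RNA (IP), the levels were 46.8 ± 12.9 CPM (SD, n = 3) and 70.1 ± 21.1 (n = 5), or 66.8% (exact permutation p = 0.161), and the groups overlapped.

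Foxp2 in the single libraries was as follows. Wild-type Input libraries held 37.7 CPM in wt734, 41.6 in wt736, 39.6 in wt785, 63.6 in wtBT13 and 51.4 in wtBT14. Heterozygous Input libraries held 23.9 CPM in het729, 28.2 in het786 and 30.7 in hetBT13, each below every wild-type Input. In IP, wild types held 60.8 CPM in wt734, 103 in wt736, 68.4 in wt785, 46.1 in wtBT13 and 71.8 in wtBT14, against 52.6 in het729, 55.9 in het786 and 32 in hetBT13. Foxp2 in heterozygotes was 53.4% of wild type among animals with BT names and 65.8% among those with number-only names in Input, and 54.3% and 69.9% in IP. The model across all genes (edgeR) gave a log2 fold change of -0.76 (SE 0.17, adjusted p = 0.501) in Input and -0.59 (SE 0.23, adjusted p = 0.981) in IP, so Foxp2 was not called in either. Over 20 alternatives in Input the adjusted p of Foxp2 ran from 0.000794 to 0.993 and the log2 fold change from -0.84 to -0.64, and 2 alternatives called the gene. In IP the log2 fold change ran from -0.74 without het786 to -0.38 without hetBT13 over 17 alternatives, of which 0 called it. The counts cover the whole gene, so a transcript that lacks deleted exons still counts, and the gene-level value is a limited check of the deletion.

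**Figure D1:**
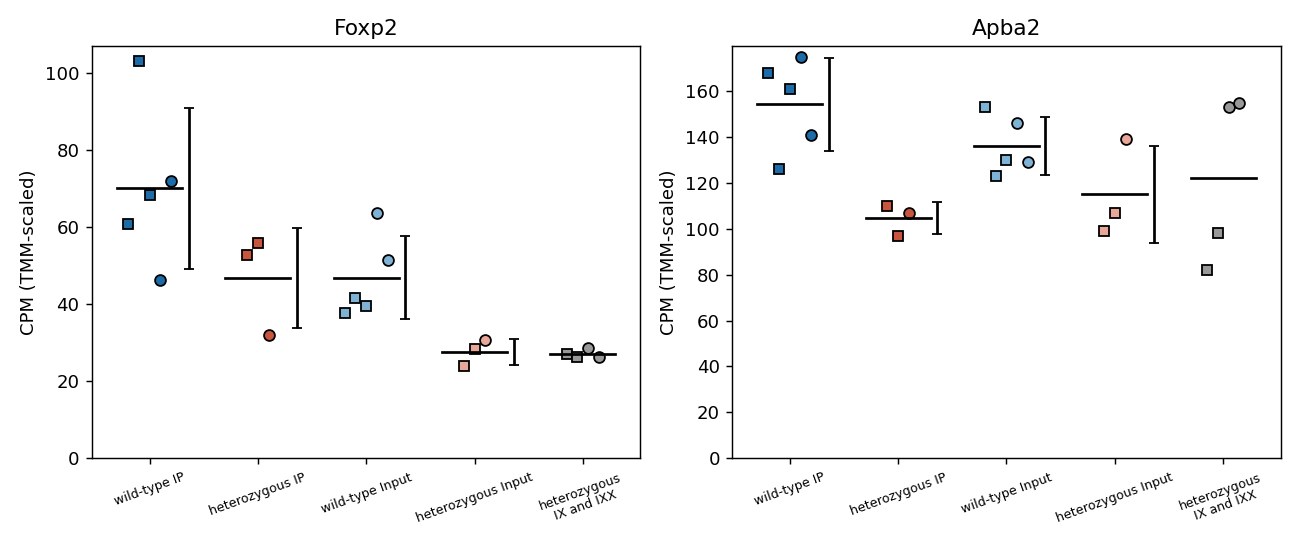
Foxp2 and Apba2 in CPM (linear axis) in each IP and Input library, with group means and SD. Every heterozygous Input value of Foxp2 (23.9 to 30.7) lies below every wild-type Input value (37.7 to 63.6), and the IP values of Foxp2 overlap.

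Apba2 (ENSMUSG00000030519, chromosome 7, 64501706 to 64753878), which encodes an adaptor protein of the presynaptic terminal, was at 105 ± 6.8 CPM in heterozygous IP (SD, n = 3) and 154 ± 20.2 in wild-type IP (n = 5), 67.9% of the wild-type level (exact permutation p = 0.0357, two-sided). The ratio was 67.7% among BT-named animals and 68.2% among number-only ones. Over all genes it was not called with edgeR (log2 fold change -0.56, SE 0.11, adjusted p = 0.981). The adjusted p of Apba2 ran from 0.047 with DESeq2, the only 1 of 17 alternatives that called it, to 1. Adjusted over the list alone, Apba2 passed on the social behaviour list (adjusted p = 0.00669) and the presynaptic list (0.00539), which is not independent evidence, since it was put on both from knowledge of the study. In Input, Apba2 was at 115 ± 21.1 CPM (SD, n = 3) against 136 ± 12.6 (n = 5), or 84.3% (exact permutation p = 0.125), with 101% among BT-named animals and 76% among number-only ones. The difference between the IP and Input effects had a log2 size of -0.30 (SE 0.13, edgeR adjusted p = 1).

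Libraries separated first by fraction and then by the form of the animals' names. The first principal component held 66% of the variance over 10865 genes and parted IP from Input, and het729 had the IP library nearest to the Input libraries, at -21.8 against -37.46 or below in the other IP libraries. The second component (6.9%) ran higher in BT-named than in number-only animals within each fraction. It also ran lower in heterozygotes than in wild types within each fraction and form of name. In IP it was -9.22 and -9.96 against -6.37 to -3.55 (number-only), and -1.16 against 12.06 and 12.5 (BT). In Input it was -3.65 and -6.03 against -1.65 to 2.01, and 9.09 against 11.44 and 27.81. The BT-named animals compared hold 1 heterozygote, and this order was not tested. Mitochondrially encoded RNA took 0.928% to 1.86% of the counts in the 8 Input libraries compared, 0.0616% to 0.127% in 7 IP libraries, and 0.398% in the IP of het729.

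**Figure D2:**
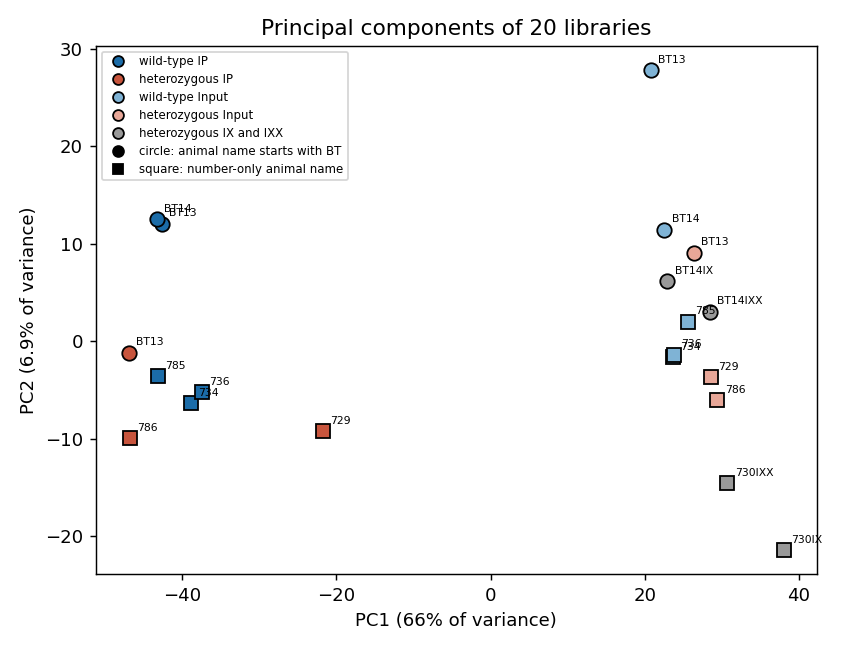
Principal components 1 and 2 (unitless scores on log2 CPM, 10865 genes) of the 20 libraries, by genotype, fraction and form of the animal's name. Component 1 (66%) parts IP from Input, and component 2 (6.9%) is higher in BT-named animals. Within each fraction and form of name, component 2 is lower in heterozygotes.

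In the IP of heterozygotes, no gene passed the threshold with edgeR, but genes of the GABA receptor and genes of astrocytes and mural cells were lower as groups by camera with its preset correlation. With a correlation estimated from the data only GABA receptors passed (adjusted p = 0.0441), and astrocytes (0.441) and mural cells (0.102) missed. All 15 GABA receptor genes had negative changes, with a median of 0.853-fold: Gabrd was at 52.3 ± 0.118 CPM against 67.2 ± 11.4 and Gabrb2 at 47.6 ± 10.7 against 63.2 ± 11.7 (SD, n = 3 and 5). Of 14 astrocyte genes, 12 were lower, with a median log2 change of -0.33, and the water channel gene Aqp4 was at 14.4 ± 1.6 against 24.7 ± 6.71 CPM. All 6 mural cell genes were lower, with a median of -0.76, and Vtn (vitronectin) was at 7.64 ± 1.37 against 13.9 ± 3.67 CPM.

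With edgeR 0 of 14755 genes passed in IP, 604 (4.09%) had an unadjusted p below 0.05, DESeq2 called 3 and limma-voom 0. The 3 called by DESeq2 were lower in heterozygotes: Mlc1 (adjusted p = 0.0188), Htra1 (0.0425) and Apba2 (0.047). Mlc1, which encodes an astrocyte membrane protein, was at 23.1 ± 8.02 against 52.9 ± 13.9 CPM (log2 -1.19, SE 0.24), and Htra1, a secreted protease gene, at 32.8 ± 7.72 against 61.4 ± 12.3 (log2 -0.90, SE 0.19). Both had an edgeR adjusted p of 0.981, as did every other gene of smallest p: Il10rb and Cyp7b1 on the lower side (log2 -1.88 and -0.94), and Sox1ot, Golga5, Btaf1, Klf6 and Hexim2 on the higher side (1.89, 0.47, 1.06, 0.29 and 0.50). Foxp1, Foxp4, Drd1, Ntsr1 and Cntnap2 had log2 changes of 0.11, 0.13, 0.01, -0.04 and -0.22, none called.

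The GABA receptor list was the only 1 of 34 lists to pass in IP both with the preset correlation of camera (adjusted p = 1.89e-06) and with a correlation estimated from the data (adjusted p = 0.0441); fry gave 0.0251. No member passed over all genes, and 0 passed adjusted over the list alone. Its mean log2 level per animal differed by -0.22 (exact permutation p = 0.0179, adjusted p = 0.304 over the lists; n = 3 and 5), -0.18 among BT-named and -0.24 among number-only animals. The adjusted p with an estimated correlation ran from 0.00712 to 0.18 over 15 alternatives, was below 0.05 in 3 of them, and was highest without het729.

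Camera with the preset correlation passed 15 lists in IP, 4 higher and 11 lower in heterozygotes, and in each of them 0 members passed over all genes. Glial and vascular lists were lower. For astrocytes the camera adjusted p was 3.44e-05 (adjusted p = 0.441 with an estimated correlation; 12 genes lower, 2 higher), and 1 gene, Aqp4, passed adjusted over the list alone. For microglia it was 3.78e-05 (adjusted p = 0.441 with an estimated correlation, 13 lower, 0 higher, median -0.41), and 1 gene, Fcrls, passed adjusted over the list alone at 4.4 ± 1.08 against 10.1 ± 2.69 CPM. For mural cells it was 5.96e-05 (adjusted p = 0.102 with an estimated correlation), and 1 gene, Vtn, passed adjusted over the list alone. Oligodendrocyte precursors (Pdgfra, Matn4, median -0.40, 6 lower, 1 higher) had 0.00378 (adjusted p = 0.441 with an estimated correlation), oligodendrocytes (Mog, Cldn11, median -0.15, 11 lower, 3 higher) 0.00435 (adjusted p = 0.564 with an estimated correlation) and endothelium (Slc2a1, Itm2a, Cldn5, median -0.45, 3 lower) 0.0473 (adjusted p = 0.553 with an estimated correlation). In these 3 lists 0 genes passed adjusted over the list alone. Without het786 the oligodendrocyte call ended (0.63, median -0.03), as did those of precursors (0.0607), microglia (0.0607, median -0.13) and endothelium (0.0986). Oligodendrocytes also missed without wtBT13 (0.0528, median -0.08), and endothelium without het729 (0.197), wt785 (0.12) or wtBT13 (0.168, median -0.28). Among calls that stayed, medians moved by more than 1.5-fold without hetBT13 for oligodendrocytes (-0.34), precursors (-0.70) and endothelium (-0.74), without het729 for oligodendrocytes (-0.31) and precursors (-0.62), without wt736 for oligodendrocytes (-0.25), without wtBT13 for precursors (-0.26) and without het786 for astrocytes (-0.22). With mitochondrially encoded RNA as a covariate, chosen after the data were examined, endothelium missed (0.108, median -0.38), as it did with the form of the names as one (0.0668, median -0.45), though the medians stayed close to -0.45. Within both forms of name the score differences of these 6 lists kept their sign.

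Among neuronal lists, ion channels (Cacna2d1, Cacna1b, median log2 -0.15, 29 lower, 7 higher) had a camera adjusted p of 0.000613 (adjusted p = 0.564 with an estimated correlation), axon guidance (Plxna4 at 20.1 ± 4.39 against 38 ± 13.9 CPM, Sema3e at 23.8 ± 2.19 against 32.7 ± 3.98, median -0.14, 28 lower, 12 higher) 0.00141 (adjusted p = 0.48 with an estimated correlation), and immediate early genes (Nr4a1, Egr2, Junb, Arc, median -0.21, 15 lower, 1 higher) 0.00448 (adjusted p = 0.564 with an estimated correlation). Upper layers (Rspo1, Otof, median -0.13, 9 lower, 2 higher) had 0.0258 (adjusted p = 0.553 with an estimated correlation). Layer 6 corticothalamic genes were higher (Tle4 at 125 ± 14.7 against 104 ± 13 CPM, median 0.16, 8 higher, 2 lower) with 0.0147 (adjusted p = 0.546 with an estimated correlation). Adjusted over the list alone, 0 genes passed in these 5 lists. Single animals ended all of these calls: axon guidance without het729 (0.144, median -0.09), ion channels without wt734 (0.0508, median -0.09), and immediate early genes without het786 (0.164) or wtBT13 (0.143), with a median of -0.13 in both. Layer 6 missed without het729 (0.116, median 0.08), het786 (0.141, median 0.10), wtBT13 (0.0779) or wtBT14 (0.0586). Upper layers missed without het729 (0.415), het786 (0.114), wt734 (0.0508) or wtBT13 (0.0694). The medians of immediate early genes were -0.35 without het729 and -0.34 without hetBT13, those of upper layers -0.21 without wt785 and -0.27 without hetBT13, and that of ion channels -0.09 without het786. Upper layers also missed with the stricter filter (0.0723, median -0.11) and with the mitochondrial covariate (0.108, median -0.12). Among BT-named animals the ion channel and upper layer scores differed the other way (0.04 and 0.02), against -0.29 and -0.37 among number-only animals, and axon guidance differed by -0.04 and -0.23.

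Mitochondrially encoded genes (median log2 1.13, 12 higher, 0 lower), nuclear genes of oxidative phosphorylation (median 0.11, 56 higher, 5 lower) and cytosolic ribosomal protein genes (median 0.08, 65 higher, 13 lower) were the higher lists besides layer 6, and none of the 3 kept both call and direction without het729. Their camera adjusted p values were 0.0133 (adjusted p = 0.675 with an estimated correlation), 3.01e-07 (adjusted p = 0.564 with an estimated correlation) and 0.00185 (adjusted p = 0.675 with an estimated correlation), and 0 genes passed adjusted over the list alone in each. Without het729 the mitochondrial median turned to -0.50 (adjusted p = 3.04e-05), the oxidative phosphorylation median was 0.02 (0.257) and the ribosomal median turned to -0.03 (0.36). The mitochondrial call also ended without wt785 (0.11) and the ribosomal call without wtBT14 (0.0906, median 0.04). The ribosomal median was 0.16 without hetBT13. With mitochondrially encoded RNA as a covariate the mitochondrial call (median 0.01) and the ribosomal call (0.236, median 0.03) ended, and that of oxidative phosphorylation stayed. The covariate is the score of the mitochondrial list itself, so the end of the mitochondrial call was fixed by construction. Among BT-named animals the mitochondrial score difference was -0.27, against 0.82 among number-only ones, the ribosomal difference was 0 against 0.10, and that of oxidative phosphorylation 0.16 against 0.05.

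**Figure D3:**
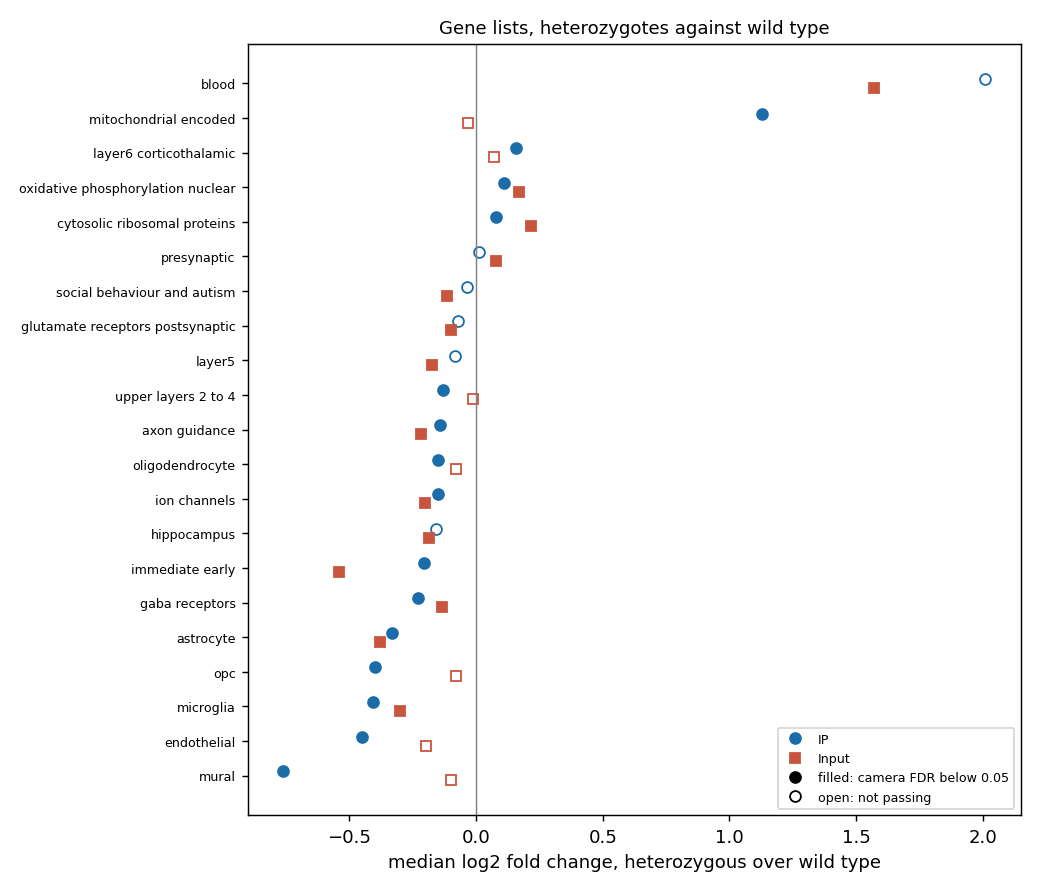
Median log2 fold change, heterozygous against wild type, of each gene list in IP and in Input, with the lists that passed camera marked. Astrocyte genes lie below 0 in both fractions (-0.33 and -0.38), and GABA receptor genes do too (-0.23 and -0.14).

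In the Input of heterozygotes, astrocyte, axon guidance, ion channel and immediate early genes were lower as groups, and ribosomal protein and oxidative phosphorylation genes higher, by camera with its preset correlation. None of these 6 lists passed with an estimated correlation (adjusted p from 0.058 to 0.478). Of 14 astrocyte genes 13 were lower, with a median of 0.77-fold: the glutamate transporter genes Slc1a2 and Slc1a3 were at 329 ± 7.07 against 454 ± 61.3 CPM and 105 ± 14.7 against 161 ± 43.1, and the connexin gene Gjb6 at 38 ± 6.59 against 57.1 ± 9.66 (SD, n = 3 and 5). Axon guidance genes had a median log2 change of -0.22, with 31 of 39 lower. Cntn1, a cell adhesion gene, was at 255 ± 21.5 against 321 ± 29.7 CPM. The transcription factor gene Junb was at 64.4 ± 15.6 against 108 ± 28.8 CPM.

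With edgeR 0 of 13870 genes passed in Input, 979 (7.06%) had an unadjusted p below 0.05, and DESeq2 and limma-voom called 0. Without the low-count filter edgeR called 28 (5 higher, 23 lower), among them Junb (adjusted p = 8.52e-05), Mfge8 (0.000127), Slc1a3 (0.00025) and Foxp2 (0.000794). Smallest p on the lower side belonged to Scd1 (27.6 ± 2.28 against 43.2 ± 3.93 CPM, log2 -0.64, SE 0.13), Itih3, Selenop, Mfge8 and Slc1a2, each with an adjusted p of 0.501 with the filter. On the higher side it belonged to Tubb5 (1070 ± 83.1 against 861 ± 47.1 CPM), Rpl9-ps6, Gm6682, Gm24187 and Sdad1, each with 0.634. Rpl9-ps6 is named as a copy of Rpl9 and Gm6682 is annotated as a processed pseudogene, so their reads cannot be placed with certainty. Foxp1, Foxp4, Drd1, Ntsr1 and Cntnap2 had log2 changes of 0.03, 0.12, -0.05, -0.50 and -0.23, none called.

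Camera with the preset correlation passed 14 lists in Input, 4 higher and 10 lower, and with an estimated correlation 0 passed, as with fry. Over all genes 0 members passed in each of them, and 12 of the 14 kept their sign within both forms of name, microglia and presynaptic genes being the exceptions. The astrocyte list had a camera adjusted p of 3.39e-07 (adjusted p = 0.168 with an estimated correlation), and 5 genes passed adjusted over the list alone: Slc1a2, Slc1a3, Ntsr2, Gjb6 and Fgfr3. It passed camera in all 18 alternatives, and its score differed by -0.28 among BT-named and -0.29 among number-only animals (pooled exact permutation p = 0.0357, adjusted p = 0.202 over the lists; n = 3 and 5), where BT-named animals hold 1 heterozygote. Of the IX and IXX libraries, which were not compared, those of hetBT14 scored 6.737 and 6.711, against 6.915 and 6.548 in the BT-named wild types, and those of het730 6.188 and 6.192, below every wild-type Input (6.548 to 6.915). Averaged per animal and included, they gave a score difference of -0.27 (exact permutation p = 0.0476, adjusted p = 0.231 over the lists; n = 5 and 5). With the IX and IXX libraries included the astrocyte median was -0.25, and with het729 and het730 left out as well -0.16 (0.032), against -0.38, and the list passed camera in both. Axon guidance had 1.01e-06 (adjusted p = 0.058 with an estimated correlation) and differed by -0.22 and -0.23 within the forms of name. Ion channels (Kcnj3, Scn8a, median -0.20, 31 lower, 4 higher) had 1.34e-07 (adjusted p = 0.168 with an estimated correlation), and immediate early genes (median -0.54, 13 lower, 3 higher) 5.73e-06 (adjusted p = 0.321 with an estimated correlation). GABA receptors (Gabbr2 at 107 ± 14.4 against 131 ± 2.42 CPM, median -0.14, 14 lower, 1 higher) had 0.000304 (adjusted p = 0.168 with an estimated correlation), and differed by -0.04 and -0.22 within the forms of name. The immediate early median was -0.35 without het786 and also without wtBT13, and that of GABA receptors -0.20 without hetBT13. Adjusted over the list alone, 0 genes passed in these 4 lists.

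The social behaviour and autism list (Scn2a, Nlgn3, Katnal2, median log2 -0.12, 24 lower, 7 higher) had a camera adjusted p of 0.000552 in Input (adjusted p = 0.168 with an estimated correlation), and so did microglia (Ctss, C1qa, median -0.30, 12 lower, 2 higher, adjusted p = 0.321 with an estimated correlation). Microglial scores differed by 0.03 among BT-named and -0.41 among number-only animals. Layer 5 (Fam84b, Sulf2, median -0.17, 8 lower, 3 higher) had 0.0187 (adjusted p = 0.168 with an estimated correlation), glutamate receptor genes (Gria4, Grm5, Gria1, median -0.10, 24 lower, 8 higher) 0.0272 (adjusted p = 0.2 with an estimated correlation) and hippocampal genes (C1ql2, Cabp7, median -0.18, 5 lower, 1 higher) 0.029 (adjusted p = 0.226 with an estimated correlation). Presynaptic genes were higher (median 0.08, 18 higher, 7 lower) with 0.0319 (adjusted p = 0.583 with an estimated correlation), and differed by 0.15 and -0.03 within the forms of name. Adjusted over the list alone, 0 genes passed in these 6 lists. Glutamate receptors missed without wt734 (0.055), wt736 (0.082, median -0.06) or hetBT13 (0.0655). Hippocampal genes missed without het786 (0.0965), hetBT13 (0.0997), wt785 (0.15) or wtBT13 (0.115). Presynaptic genes missed without het786 (0.16), hetBT13 (0.763, median 0.04), wt785 (0.0827) or wtBT13 (0.26, median 0.04), with library totals as the only scaling (0.143, median 0.02) and in the 4-group fit (0.0595), and their median was 0.14 without het729 and 0.13 without wtBT14. With the IX and IXX libraries included, layer 5 (0.0736), glutamate receptors (0.112), hippocampal (0.377) and presynaptic genes (0.611) missed, and with het729 and het730 left out as well, a fit chosen after the data were examined, microglia (0.641) and GABA receptors (0.15) missed too. Hippocampal genes also missed with the stricter filter (0.121) and with haemoglobin RNA as a covariate (0.0552, median -0.23).

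Ribosomal protein genes were higher in heterozygous Input with a median log2 change of 0.22 (77 higher, 1 lower; camera adjusted p = 4.18e-13, adjusted p = 0.478 with an estimated correlation), and Rpl6 was at 103 ± 10.1 against 80.2 ± 16 CPM. Nuclear oxidative phosphorylation genes had a median of 0.17 (61 higher, 0 lower, 1.3e-12, adjusted p = 0.359 with an estimated correlation), and Ndufs7 was at 375 ± 11 against 324 ± 25.7 CPM. Haemoglobin and other blood genes had a median of 1.57 (5 higher, 0 lower, 0.000207, adjusted p = 0.321 with an estimated correlation), with 817 CPM of Hba-a1 in het729 behind a group mean of 355 ± 400 against 126 ± 38.5. Without het729 the blood median was 0.06 (0.613), and with haemoglobin RNA as a covariate -0.05 (0.919). That covariate is the score of the blood list itself, so it removes the difference by construction. The score of blood genes differed by 0.30 among BT-named and 1.4 among number-only animals. Ribosomal and oxidative phosphorylation medians were 0.14 and 0.10 without het729 and 0.11 and 0.10 without wtBT13, and the latter was 0.27 without hetBT13. Adjusted over the list alone, 0 genes passed in these 3 lists. In lists that missed camera, 1 gene each passed adjusted over the list alone in Input: Itm2a on the endothelial list and Cav2 on the list of genes near Foxp2.

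Ribosome-bound RNA of wild types was rich in layer 6 corticothalamic and axon guidance genes and poor in astrocyte, oligodendrocyte, microglial, striatal, interneuron, blood, mitochondrial and nuclear RNA by camera with its preset correlation, but with an estimated correlation 0 lists passed. Ntsr1, a receptor gene used as a marker of layer 6 corticothalamic neurons, was 8.53-fold higher in IP than in Input (38.9 ± 4.43 against 4.52 ± 0.798 CPM; SD, n = 5 pairs). Eprs, a tRNA synthetase gene, was 5.38-fold higher (418 ± 43.7 against 77.4 ± 12.6 CPM). The myelin gene Mal fell to 0.238-fold (58.2 ± 17.7 against 239 ± 49.2 CPM), the astrocyte gene S100b to 0.307-fold and the interneuron gene Vip to 0.217-fold. In heterozygotes Ntsr1 was 11.7-fold higher (37.9 ± 3.63 against 3.09 ± 1.12 CPM; n = 3 pairs).

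The paired edgeR model called 8067 of 15145 genes in wild types (53.3%), 4254 higher and 3813 lower in IP. In heterozygotes it called 6643 (43.9%), 3358 higher and 3285 lower. Both genotypes shared 2935 genes called higher and 2881 called lower, where 943 and 827 would be shared if the calls were independent, and 1 gene was called in opposite directions. Scaling by library totals alone shifted the median log2 change of all genes to 0.26 in wild types and 0.30 in heterozygotes, from 0.03 and 0.04. The calls became 6404 higher and 2407 lower in wild types, and 5759 higher and 1918 lower in heterozygotes. Changes are therefore given relative to the bulk of genes. Among the largest increases were those in Tmem255b (9.02-fold; its exons overlap Gas6), Trbj2-3, Plec (6.39-fold; overlaps Parp10), Aldh3a1, Cbln1, Eprs, Cldn1 and Prpf8 (5.09-fold). Largest decreases were in the small RNA genes Gm24514, Gm26461, Rn7s6, Rn7s2 and Rn7s1, the pseudogene Gm11410, mt-Atp8, mt-Nd3, Cdr1 and mt-Atp6, with log2 changes from -7.75 for Gm24514 to -4.89 for mt-Atp6. The Rn7s genes are near-identical, and the protocol keeps no strand, so overlapping genes cannot be told apart. Foxp2 was higher in IP by a log2 of 0.56 in wild types (adjusted p = 0.069) and 0.74 in heterozygotes (adjusted p = 0.0987) and was not called. Wild-type Foxp2 was called with 5 alternatives, at adjusted p values of Foxp2 from 1.36e-06 without the low-count filter to 0.019 without the animal block, and 0.00018 without wtBT13. Heterozygous Foxp2 was called with 6, from 1.14e-05 without the low-count filter to 0.0345 without the animal block, among them the fits without wt736 (0.0281) and wtBT13 (0.00407), which share their spread with heterozygotes. Foxp4 was called higher (0.75) and Foxp1 (-1.17) and the dopamine receptor gene Drd1 (-0.82) lower, while Apba2 (0.16) and Cntnap2 (-0.19) were not called.

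In wild types 18 lists passed camera with the preset correlation, 6 higher and 12 lower in IP. None passed with an estimated correlation, and fry, which does not compare a list with other genes, passed 30. Layer 6 corticothalamic genes had a median log2 change of 0.81 (7 up, 1 down, 2 not passing over all genes; 9 of 10 adjusted over the list alone; camera adjusted p = 0.00113, adjusted p = 0.225 with an estimated correlation), led by Ntsr1 and Tle4 (1.23), while Foxp1 was lower. Axon guidance genes had 0.54 (22 up, 4 down, 14 not passing; 27 adjusted over the list alone, 9.57e-05, adjusted p = 0.216 with an estimated correlation), with Nrp1 at 1.41 and Slit1 at 1.54. The social behaviour list had 0.41 (17 up, 4 down, 10 not passing; 23 adjusted over the list alone, 0.00357, adjusted p = 0.266 with an estimated correlation). Glutamate receptors (15 up, 3 down, 14 not passing; 18 adjusted over the list alone) had 0.0201 (adjusted p = 0.275 with an estimated correlation), ion channels (19 up, 4 down, 13 not passing; 23 adjusted over the list alone) 0.0265 (adjusted p = 0.41 with an estimated correlation) and glutamatergic neurons (8 up, 2 down, 1 not passing; 10 adjusted over the list alone) 0.0359 (adjusted p = 0.405 with an estimated correlation). Slc17a7 was up by 0.68 and Nrgn down, at -0.87. Without wtBT13 the glutamatergic call ended (0.0929), as it did with the stricter filter (0.0563) and without the animal block (0.0545), and without wt734 (0.0559) or wt785 (0.0513) that of ion channels, as with the stricter filter (0.0544).

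Lists lower in wild-type IP were led by mitochondrially encoded genes, with a median log2 change of -4.60 (0 up, 13 down; 13 adjusted over the list alone; camera adjusted p = 1.51e-12, adjusted p = 0.225 with an estimated correlation). Ribosomal protein genes had -0.45 (1 up, 55 down, 22 not passing; 56 adjusted over the list alone, 5.39e-11, adjusted p = 0.334 with an estimated correlation) and oxidative phosphorylation genes -0.33 (2 up, 44 down, 15 not passing; 50 adjusted over the list alone, 3 up and 47 down, 1.29e-09, adjusted p = 0.334 with an estimated correlation). Oligodendrocyte genes had -1.72 (12 down, 2 not passing, 8.04e-10, adjusted p = 0.216 with an estimated correlation), astrocyte genes -1.01 (1 up, 11 down, 2 not passing, 3.58e-06, adjusted p = 0.216 with an estimated correlation) and microglial genes -1.30 (10 down, 4 not passing, 0.000231, adjusted p = 0.237 with an estimated correlation). Interneuron genes had -1.10 (1 up, 14 down, 2 not passing, 3.58e-06, adjusted p = 0.225 with an estimated correlation), and the exception, Reln, was 4.56-fold higher. Striatal genes, whose tissue was dissected away per the labels, had -1.18 (11 down, 3 not passing, 3.58e-06, adjusted p = 0.216 with an estimated correlation), with Ppp1r1b at 229 ± 21.4 CPM in IP and 813 ± 79 in Input. Dopamine signalling genes had -0.32 (6 down, 4 not passing, 0.0131, adjusted p = 0.275 with an estimated correlation), and of its members Adcy5 and Gnal were no longer called with library totals. Nuclear RNAs such as Meg3 and Miat had -1.96 (6 down, 3.58e-06, adjusted p = 0.216 with an estimated correlation), and blood genes -3.19 (5 down, 3.73e-05, adjusted p = 0.216 with an estimated correlation). Presynaptic genes had -0.39 (5 up, 14 down, 6 not passing, 6 up and 14 down adjusted over the list alone, 0.0225, adjusted p = 0.585 with an estimated correlation), with Vamp1 at -1.46 and Unc13a at 1.56. Without wtBT14 the presynaptic call ended (0.0538). In the oligodendrocyte, astrocyte, microglia, interneuron, striatal, dopamine, nuclear RNA and blood lists the counts adjusted over the list alone equalled those over all genes.

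In heterozygotes 18 lists passed camera, 5 higher and 13 lower, and 17 of them were those of wild types with the same directions. With an estimated correlation 0 passed, with adjusted p values from 0.199 to 0.489 with an estimated correlation. Upper layer genes were lower (median -0.60, 1 up, 6 down, 4 not passing, 2 up and 6 down adjusted over the list alone; camera adjusted p = 0.0208), with Calb1 at -1.20, and missed without het729 (0.0967). Dopamine signalling genes missed without the low-count filter (0.0602). Glutamatergic neuron genes missed (0.0508). The median of mitochondrially encoded genes was -3.79.

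**Figure D4:**
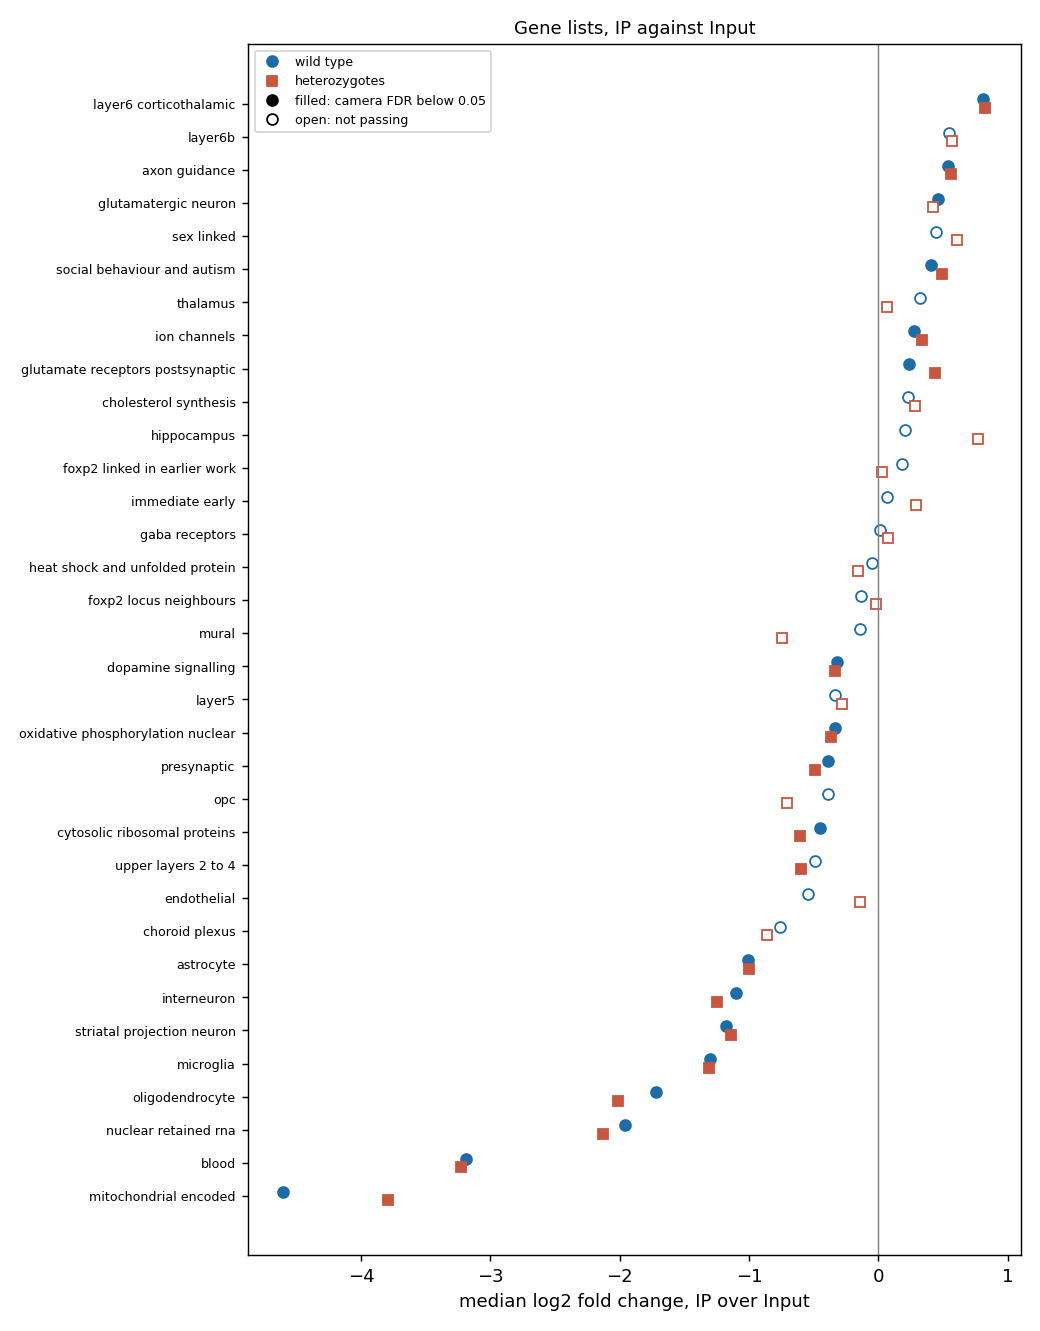
Median log2 IP to Input ratio of each gene list in wild types and in heterozygotes, relative to the bulk of genes. Layer 6 corticothalamic genes lie at 0.81 and 0.83 and mitochondrially encoded genes at -4.60 and -3.79.

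The ratio of IP to Input in wild types went with the length of the coding region. With protein-coding genes parted into 5 classes of coding length, genes called higher in IP made up 17.3% of the shortest class (median 543 nucleotides) and 51.6% of the longest (3502.5), and genes called lower 41.4% and 7.67%. Spearman's rho across 12762 genes, which are not independent replicates, was 0.333 for coding length, -0.119 for the length of the 3' untranslated region and 0.0812 for GC content.

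**Figure D5:**
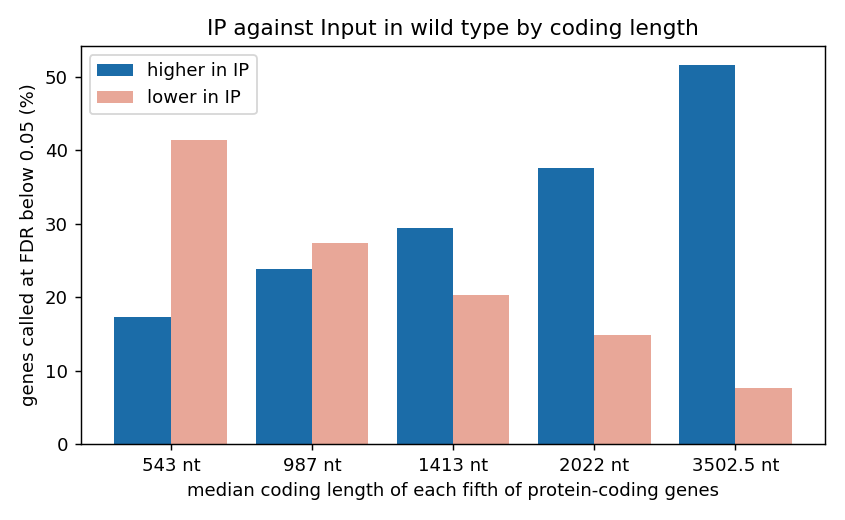
Share of protein-coding genes (percent) called higher or lower in wild-type IP than in Input in each of 5 classes of coding length. Genes called higher rise from 17.3% to 51.6%, and genes called lower drop from 41.4% to 7.67%.

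Whether the genotype effect differed between fractions was tested in the paired fit, where mitochondrially encoded genes had larger and ribosomal protein genes smaller heterozygous effects in IP than in Input by camera with its preset correlation. With an estimated correlation both missed (adjusted p = 0.846), and without het729 the mitochondrial difference turned. No single gene passed: edgeR called 0 of 15145, 482 (3.18%) had an unadjusted p below 0.05, and DESeq2 and limma-voom called 0. The mitochondrial list had a median log2 difference of 0.58 (13 up, 0 down; camera adjusted p = 1.06e-05, adjusted p = 0.846 with an estimated correlation), which turned to -0.56 without het729 (1.21e-07) and was 1.23 without het786 and 1.08 without hetBT13. Ribosomal protein genes had -0.15 (70 down, 8 up, 2.31e-05, adjusted p = 0.846 with an estimated correlation) and missed without het786 (0.133, median -0.08) or wtBT13 (0.256, median -0.07). Immediate early genes had 0.21 (13 up, 3 down, 0.0055, adjusted p = 0.566 with an estimated correlation) and missed without het786 (0.133) or wtBT13 (0.0729). Mural genes had -0.46 (6 down, 0 up, 0.0483, adjusted p = 0.566 with an estimated correlation) and missed without het786 (0.0708), hetBT13 (0.627, median -0.20), wt736 (0.057), wtBT13 (0.0962) or wtBT14 (0.0991). The immediate early (0.167) and mural (0.0729) calls ended without the animal block, and mural genes missed with the stricter filter (0.0608). In these 4 lists 0 members passed over all genes and 0 adjusted over the list alone. Matn4, on the precursor list, passed adjusted over the list alone. For the GABA receptor (0.491) and astrocyte (0.79) lists the camera adjusted p gave no difference between fractions past the threshold.

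Among the lists that passed in no comparison, genes near Foxp2 on chromosome 6 had camera adjusted p values of 0.326 in IP and 0.141 in Input, and genes linked to Foxp2 in earlier work 0.675 and 0.997. The respective values were 0.657 and 0.641 for layer 6b, 0.416 and 0.319 for choroid plexus, 0.624 and 0.239 for thalamus, 0.326 and 0.319 for heat shock and unfolded protein genes, 0.987 and 0.791 for sex-linked genes, and 0.326 and 0.0603 for cholesterol synthesis. The Foxp2-linked list pointed down in wild-type IP against Input by camera (0.609) with a median log2 change of 0.18 and a mean of 0.09.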

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

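The tests for fewer non-neuronal cells, for unbound RNA in the IP of het729, for loss of short transcripts and for clock genes in IP, and the covariate of mitochondrially encoded RNA, were chosen after the results were seen. In 426 checks of groups of 4 or 5 libraries, 15 found a library far from the others (its gap to the nearest, as a share of the group's range, above Dixon's critical value). Chance would flag about 5% of independent checks, and the total of 15 is not above that rate. The checks share libraries and genes, so this total cannot tell whether flags gathered in 1 animal are chance. Of the 15, 8 concerned wtBT13. In its IP the immediate early score was 5.83 against 4.93 to 5.11 (share 0.797), the heat shock score 5.33 against 5.02 to 5.06 (0.879) and Btg2, an early response gene, 86.3 CPM against 34.2 to 41.2 (0.864). Its Input had 117 CPM of Btg2 against 31.8 to 48.9 (0.801), 42.8 of Egr2 against 5.08 to 10.6 (0.853), 537 of Penk against 374 to 410 (0.779), 936 of Camk2a against 1360 to 1500 (0.764), and a mitochondrially encoded score of 8.33 against 9 to 9.27 (0.716).

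In wild-type IP, Foxp4 was at 24.2 CPM in wtBT14 against 34.2 to 35.7 (share 0.868) and Prpf8 at 171 in wt736 against 228 to 238 (0.852). In wild-type Input, Vtn was at 17.6 CPM in wt734 against 11.3 to 12.9 (0.744) and Gabbr2 at 127 in wtBT14 against 132 to 133 (0.769). Among the IX and IXX libraries, Scn2a was at 149 CPM in het730IXX against 170 to 171 (0.931), Crym at 108 in hetBT14IX against 116 to 117 (0.859) and Lhx6 at 33.4 in het730IX against 37.2 to 37.8 (0.856). In both libraries of het730, which the comparisons did not use, blood genes scored 8.59 and 8.6 against 4.81 to 6.1 in wild-type Input, and nuclear RNAs 6.36 and 6.49 against 5.73 to 6.03.

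The genotype effects in IP and Input differed past the threshold of camera with its preset correlation for mitochondrially encoded (1.06e-05), ribosomal protein (2.31e-05), immediate early (0.0055) and mural genes (0.0483). With an estimated correlation none of these differences passed, and leaving out het729 turned the mitochondrial one from 0.58 to -0.56.

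Astrocyte genes were lower in heterozygotes in both fractions by camera with its preset correlation, though not with an estimated one. With the form of the animals' names as a covariate the list still passed in Input at the preset correlation (3.92e-07). The score differed by -0.28 among BT-named animals, with 1 heterozygote, and by -0.29 among number-only ones. These values argue against the form as the whole source, but only for the preset correlation. With an estimated one the unadjusted camera p of that fit was 0.0368, and the list passed in 0 of 18 alternatives. Of the IX and IXX libraries those of hetBT14 scored within the range of BT-named wild types and those of het730 below every wild-type Input. Less unbound RNA in heterozygous IP is not excluded for the IP part. With mitochondrially encoded RNA as a covariate the list still passed there at the preset correlation (5.19e-05), but its unadjusted camera p with an estimated correlation was 0.0788. This covariate is highest in het729, whose oligodendrocyte score lay within the range of the other IP libraries, so it may not follow glial RNA. Fewer cells of every non-neuronal type in the heterozygous lysates cannot be told apart from a change in astrocytes: the astrocyte score relative to the oligodendrocyte score differed by -0.18 in Input (exact permutation p = 0.0714, n = 3 and 5), the oligodendrocyte score by -0.12 (exact p = 0.482) and the microglia score by -0.25 (exact p = 0.143), near the -0.30 of astrocytes. A genotype effect on astrocytes may remain, as a hypothesis that these 8 animals leave open.

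The IP library of het729 stood between the other IP libraries and Input. If unbound lysate RNA were left in it, the shares of Input RNA needed for mitochondrially encoded (22.9%), haemoglobin (16.4%) and oligodendrocyte RNA (7.32%) should be alike, and the largest was 3.13 times the smallest. The first 2 lay above the highest other IP libraries (0.0285% and -10.1%). This gap is partly built in: each library's baseline was the mean of the other IP libraries, so het729 raised the baseline of the rest and lowered their shares. The oligodendrocyte share lay within those of the other IP libraries (up to 9.07%, SD 7.85), so its size is not known well enough to decide. Carry-over may therefore explain this library but cannot be told apart from other changes in it. No biological explanation was tested.

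Libraries of BT-named and number-only animals differed within both genotypes, with 811 of 14203 genes called in Input (200 higher, 611 lower in BT, genotype as a covariate) and 86 of 15176 in IP (45 higher, 41 lower). By camera with its preset correlation, ribosomal protein and oxidative phosphorylation genes were lower in BT-named Input (medians -0.50 and -0.35) and immediate early genes higher (0.55). With an estimated correlation none of the lists passed (adjusted p = 0.362, 0.362 and 0.457). A different time of day cannot be told apart. In Input the clock genes fell short of what it predicts: the median size of change of 16 clock genes was 0.111, at percentile 21.4 of 10000 random lists (95th percentile 0.208, SD 0.038), with 0 called. In IP the clock genes lay at percentile 83.4, within 1 SD of the 95th, and Per1 was called (log2 0.75, adjusted p = 0.0314). Both fractions of an animal come from 1 lysate, so the Input result alone cannot decide. Loss of short transcripts in library preparation is consistent with the rank correlation across 12009 genes of transcript length with the difference in Input (Spearman's rho 0.129), but in IP rho was -0.03 over 11909 genes, and genes are not independent replicates. No biological explanation was tested, and the meaning of the names is not given in the sources used here.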

How the results depend on the processing

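The covariates of mitochondrially encoded and haemoglobin RNA and the fit with the IX and IXX libraries but without het729 and het730 were chosen after the data were examined. For genotype in IP, edgeR called 0 genes with RLE or library-total scaling, without the filter, with the stricter filter, with the form of the names or mitochondrially encoded RNA as a covariate and in the 4-group fit, as did limma-voom (515 to 1009 genes at an unadjusted p below 0.05). In Input the count was 0 with both scalings, the stricter filter, the form of the names or haemoglobin RNA as a covariate, the 4-group fit, DESeq2, limma-voom and the IX and IXX libraries with or without het729 and het730 (563 to 1533 genes). DESeq2 called 3 genes in IP. Without the low-count filter 28 were called in Input and 11 in the interaction, and with the IX and IXX libraries and the form of the names as a covariate 2 were called in Input, Foxp2 (-0.76) and Rpl9-ps6 (0.56). The cause was not tested. Leaving out each animal gave 0 to 0 genes in the genotype comparisons and the interaction, 7156 to 8145 in wild-type enrichment and 4732 to 6906 in heterozygous enrichment.

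Lists depended most on the correlation between genes. With an estimated correlation 1 list passed in IP in place of 15, and 0 in Input, in either enrichment and in the interaction. Fry, which does not compare a list with other genes, passed 1, 0, 30, 30 and 0. Why it passed fewer lists than camera in the genotype comparisons and the interaction was not tested. In Input 7 lists passed in place of 14 with the IX and IXX libraries included and het729 and het730 left out together. Leaving out each animal gave 10 (without het786 or wtBT13) to 17 lists in IP, 12 to 17 in Input, 17 to 18 and 17 to 19 in the enrichments, and 1 (without wtBT13) to 10 (without het729) in the interaction.

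Without the animal block 7552 genes were called in wild types, 6130 in heterozygotes and 0 in the interaction, with 17, 18 and 2 lists passing. No paired analysis was possible because, among the animals compared, heterozygotes and wild types share only the number BT13, so the genotype comparisons had no block. With the IX and IXX libraries included they also share BT14.

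Directions turned in 4 cases. Over the animals left out, the median ran from -0.497 (without het729) to 1.48 for mitochondrially encoded genes and from -0.0259 (without het729) to 0.163 for ribosomal protein genes in IP, and from -0.564 (without het729) to 1.23 for mitochondrially encoded genes in the interaction. With the IX and IXX libraries included and het729 and het730 left out, blood genes in Input turned to -0.129, against 0.0613 without het729 alone. All 4 left out libraries high in mitochondrially encoded or haemoglobin RNA, but the cause was not tested. Of 996 values of lists under alternatives, these 4 among them, 911 kept direction and side of the threshold and 81 lost the call. Of 5469 values of named genes 5433 stayed on the same side of the threshold, and 31 gained and 5 lost a call. Among values called in the main fit or the alternative 0 turned. For genes called in neither, a change of direction was not counted. Small changes can be missed: on simulated data with the same totals and groups, changes of 1.5 fold were recovered in 23.1% of cases in IP and 42.4% in Input. The simulations did not vary library totals (2689544 to 5754169 counts), so the part of depth in this limit was not tested.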

Other observations

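The test of coding length among glial and vascular markers and the counts of other splits were planned before their outcome was seen, except the counts for single lists, which were added after it. Genes with longer coding regions had higher IP to Input ratios. A candidate explanation is that the pull-down favours longer coding regions, which carry more ribosomes, whatever the cell type. Among 58 markers of glia and vessels the log2 IP to Input ratio also rose with coding length (Spearman's rho 0.674 across genes, which are not independent replicates, permutation p = 1e-05, the smallest 100000 permutations can give). These markers pool several cell types, and the permutations mixed genes across them, so this test cannot part length from differences between those cell types. Longer 3' untranslated regions are argued against: in 1 rank regression with both lengths their slope was -0.156, against 0.349 (SE 0.00828) for coding length. Such a bias could add to list results of IP against Input, which may mix length with cell type. The lengths of the genes on each list were not compared.

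The groups were compared with other splits of the same libraries. With 0 genes in the real split for genotype in IP (highest other 125), in Input (highest other 675) and in the interaction (highest other 164), all 56 splits reach the real count by definition, so these counts say nothing about chance. At an unadjusted p below 0.05, 31 of 56 splits gave at least the real 604 genes in IP, 12 at least the 979 in Input and 41 at least the 482 in the interaction. In each case the highest count came from the split that follows the form of the names, which points to a structure of the samples. With that form as a covariate, genotype called 0 genes in IP and 0 in Input. For lists, other splits passed a median of 9 in IP, 8 in Input and 6 in the interaction, and 5 of 56 splits gave at least the real 15 in IP (highest other 17) and 46 of 56 at least the real 4 in the interaction (highest other 14), where chance is not excluded. In Input 3 of 56 splits gave at least the real 14 (highest other 17), and chance is not excluded there either. For the GABA receptor list with an estimated correlation, the unadjusted p of the real split was the smallest of the 56 in IP (0.0013, smallest other 0.0291) and in Input (0.0115, smallest other 0.0136). This list was picked because it passed in the real IP split, so these ranks do not exclude chance. Both fractions are of the same animals, so the Input rank is not separate support. The exact permutation p of its score, adjusted over the lists, was 0.304 in IP and 0.122 in Input. For the astrocyte list with the preset correlation, 6 of 56 splits gave a p as small as the real one in IP (3.04e-06, smallest other 3.44e-09) and 2 of 56 in Input (3.99e-08, smallest other 4.39e-12).

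For IP against Input in wild types, 1 of 100 splits, the real one, gave as many as 8067 genes (highest other 2646). Most of these splits leave both libraries of some animals on 1 side, so fewer pairs inform the fit and fewer genes can be called. The other 12 drawn that part all pairs, as the real one does, gave at most 0 genes. They are too few for a share under 0.05, so this test cannot exclude chance. For its 18 lists 7 of 100 splits gave as many (highest other 18), but the other 6 part several pairs all in 1 direction and so refit the real contrast in fewer animals, and the count says nothing about chance. The remaining splits reached at most 17. For heterozygotes 10 splits are too few for a share under 0.05, with 6643 genes in the real split and 0 in the highest other, and 18 lists against 17, each reached by 1 split.

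Foxp2 in the IX and IXX libraries, which no comparison used, was at 27.1 CPM in het730IX, 26.2 in het730IXX, 28.7 in hetBT14IX and 26.3 in hetBT14IXX. With these averaged per animal, heterozygous Foxp2 was 27.4 ± 2.47 CPM (SD, n = 5) against 46.8 ± 10.8 (n = 5), 58.6% of wild type (exact permutation p = 0.00794). This is the smallest p that the two-sided test allows with groups of equal size, where each split has a mirror image. Apba2 was 118 ± 27.4 against 136 ± 12.6 CPM in the same comparison (86.4%, exact permutation p = 0.206). Selenop, which encodes a selenium transport protein, was at 156 ± 31.3 CPM over these 4 libraries of 2 animals, against 110 ± 1.8 in the other heterozygous Input (n = 3) and 150 ± 10.7 in wild-type Input (n = 5). Between the IX and IXX libraries of 1 animal, counts varied by a chi-square per degree of freedom of 1.96 (hetBT14) and 2.67 (het730), and between Input libraries of different animals in 1 group by 2.13 to 8.52.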
